A study of Homo sapiens with 4 samples.

How the data were processed

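RNA of the human breast cancer line MDA-MB-231 was measured on 4 Affymetrix U133A_2 arrays with 1 colour and a biotin label. There were 2 groups of 2 arrays, cells kept with CXCL12 and IGF1 and cells kept without them, and each group had an array A and an array B. The series design calls the members of a group biological replicates. The labels do not say whether A and B mark a shared culture or day, or at which point of the selection and later expansion the RNA was taken.

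The table analysed holds log2 values that the authors made with RMA in the affy package, per the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays and summarises the probes of a set. The versions and the probe definition were not given in the sources used here. The table has 22277 probe sets in 4 columns, and 0 columns of other samples. Scanner files and detection calls were not used here, so a low value was not tested against its background. The number of arrays limits the precision.

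Probe sets were named from the platform's annotation table, in which 19064 sets had 1 gene, 1043 had several and 2108 were not named, besides 62 control sets. The gene identifiers of 19052 of the 19064 sets matched the RefSeq gene table of GRCh38.p14, and 0 symbols changed. Sets with several genes or none were left out of the gene test and fitted separately. Sets in the lowest 25% of mean log2 value, under 4.14, were also left out, which left 14664 sets. Each gene was then represented by its brightest set, and by a set marked as cross-hybridising (a name ending in x_at) only where it had no other. This gave 9623 genes.

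The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with the Benjamini-Hochberg adjustment over the 9623 genes and a threshold of 0.05. All differences are values with the factors minus values without them, on the log2 scale. With 2 arrays against 2, an exact permutation test of a single gene cannot give a p below 0.333, so single genes were tested in the shared model alone. The fit had 2 residual and 2.7 prior degrees of freedom.

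A total of 35 gene lists was fixed, and 34 of them had at least 5 measured genes, with 717 of 911 list genes measured. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 34 lists. Camera compares the genes of a list with all other measured genes, and fry tests a list alone. Members were also adjusted over the list alone. That adjustment was made within each list, with no correction over the 34 lists, and 5 lists had a member past it.

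The tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined, with 1 alternative added later. The rule took the genes past the adjusted threshold and, where fewer than 8 in a direction passed, those with the smallest p until 8 were reached. It also took 7 genes of the CXCL12 and IGF1 pathways and the largest differences of each list described. VCAM1, IL11, TOB1, PLK2, CRIM1, GADD45A, ANKRD1 and IGFBP3 were named after their values were seen. The alternatives were no filter or a stricter filter on dim sets, median centring, cyclic loess, a trended robust prior, other ways to represent a gene, array weights, the letter as a block, each array left out, and a size threshold.

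The steps were tested on 20 simulated data sets of the same 9623 genes with 200 changed genes of mixed sizes. At 2 arrays against 2, limma recovered 51.0% of genes changed by 1 log2, 91.6% of those changed by 2 and 98.9% of those changed by 4. There were 8.45 false calls per set. The changes of 2 and 4 log2 ease the adjusted threshold for those of 1 log2, and no array-wide variation was simulated. The recovered shares therefore do not show how many changes of 1 log2 could be found in the real data. Camera at the preset correlation found 100% of simulated lists of 20 genes shifted by 0.5 log2 and 0% of unshifted lists, at an unadjusted p under 0.05. The simulated genes were drawn independently of each other. These rates therefore do not cover real lists whose genes vary together, where the estimated correlation reached 0.60 (ATF4 targets).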

Results

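The data covered MDA-MB-231, an established human breast cancer line of the triple-negative type. The cells had been kept for 3 weeks in medium with 0.2% serum. The medium of one group held the chemokine CXCL12 at 30 ng/ml and the growth factor IGF1 at 10 ng/ml, and that of the other held neither. According to the series design, the surviving cells were then grown out in 10% serum. Each group had 2 arrays, called here factor arrays A and B and no-factor arrays A and B. The median log2 value over all probe sets was 5.87 on no-factor array A, 5.88 on no-factor array B, 5.92 on factor array A and 5.92 on factor array B.

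The comparison asked how the expression of cells selected with CXCL12 and IGF1 differed from that of cells selected in low serum alone. The series title links this selection to the ability to form bone metastases. No single gene passed the test over all genes, so the values of genes are given as measured differences. Of the 16 genes with the smallest p, 8 in each direction, PTPRN2, a phosphatase-like protein of secretory vesicles, had the widest gap and measured 4.07-fold higher with the factors. KLF5, a zinc finger transcription factor, measured 2.82-fold lower on 1 of its 2 probe sets, and SEC24D, a coat protein of vesicles leaving the endoplasmic reticulum, 2.31-fold lower on its brightest set. As a group, inhibitors of the cell cycle and genes of quiescence fell with the factors, and targets of the transcriptional coactivator YAP fell to a smaller extent, both in camera at a preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.999 each) and in fry (adjusted p = 0.19 and 0.949). The estimated correlation was -0.017 for the quiescence list, below the preset value, and 0.23 for the YAP list. Every list had an adjusted p of 0.999 in that version of camera. It relies on the 2 residual degrees of freedom and so had little power. The list of genes associated with bone metastasis did not pass the test.

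Of the 9623 genes tested, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.349. At an unadjusted p under 0.05 there were 1220 genes, 640 higher and 580 lower, where chance alone gives 481. After median centring the split was 425 higher and 710 lower, and after cyclic loess 417 higher and 687 lower. Both factor arrays lay above both no-factor arrays in 30.0% of genes and below them in 17.2%, where chance gives 16.7% for each direction. That chance share assumes no offset between the arrays. The medians were 5.87 and 5.88 on the no-factor arrays and 5.92 on each factor array, and the separation was not recounted after centring. The difference exceeded 1 log2 in 35 genes upward and in 35 downward. The 1220 genes became 372 without no-factor array A and 813 without no-factor array B. The 640 higher genes became 126 without no-factor array A, 385 without no-factor array B and 417 without factor array A, and the 580 lower genes became 246 without no-factor array A.

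Among the 8 genes with the smallest p upward, PTPRN2 (Entrez gene 5799) measured 4.73 ± 0.27 (SD, n = 2) without the factors and 6.75 ± 0.22 (SD, n = 2) with them. The difference was 2.03 log2 with a standard error of 0.19 and an adjusted p of 0.349 in limma, and further sets of PTPRN2 differed by 1.75 and, for its x_at set, by 0.47. PAPPA, a protease that cleaves IGF-binding proteins, was 0.80 higher on its tested set and 0.10 on a dimmer one. IGFBP4, the binding protein that PAPPA is best known to cleave, had a difference of 0.57 with a standard error of 0.26, which became 0.26 without factor array A. POLRMT, the RNA polymerase of mitochondria, differed by 0.80, and the calcium-activated potassium channel KCNN4 by 0.62. The retinoic acid receptor RARG differed by 0.62 on its tested set and by 0.19 and -0.16 on dimmer ones. The orphan receptor GPR27 (0.73), the homeobox gene ALX4 (0.70) and THEM6 (0.62) completed the 8.

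Among the 8 genes with the smallest p downward, SEC24D (Entrez gene 9871) measured 9.97 ± 0.06 (SD, n = 2) without the factors and 8.76 ± 0.05 (SD, n = 2) with them. Its difference was -1.21 with a standard error of 0.11 and an adjusted p of 0.349 in limma, while a pair of dimmer SEC24D sets gave 0.02 and -0.19. KLF5 (Entrez gene 688) measured 8.07 ± 0.19 (SD, n = 2) without and 6.57 ± 0.08 (SD, n = 2) with the factors, a difference of -1.50, but its other set, of similar brightness, gave 0.03. TANK, a regulator of NF-kB signalling, differed by -1.05 on its tested set and by -0.05 and -0.47 on others. BLZF1, a golgin of the Golgi apparatus, differed by -0.99 and on a further set by -1.17. GBP1, an interferon-induced GTPase, differed by -1.11 and on its x_at set by -0.46. SOAT1, which esterifies cholesterol, differed by -1.03, the zinc finger gene ZBTB10 by -1.09 and PCNX4 by -1.34. The adjusted p was 0.349 in limma for each of these 16 genes.

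**Figure D1:**
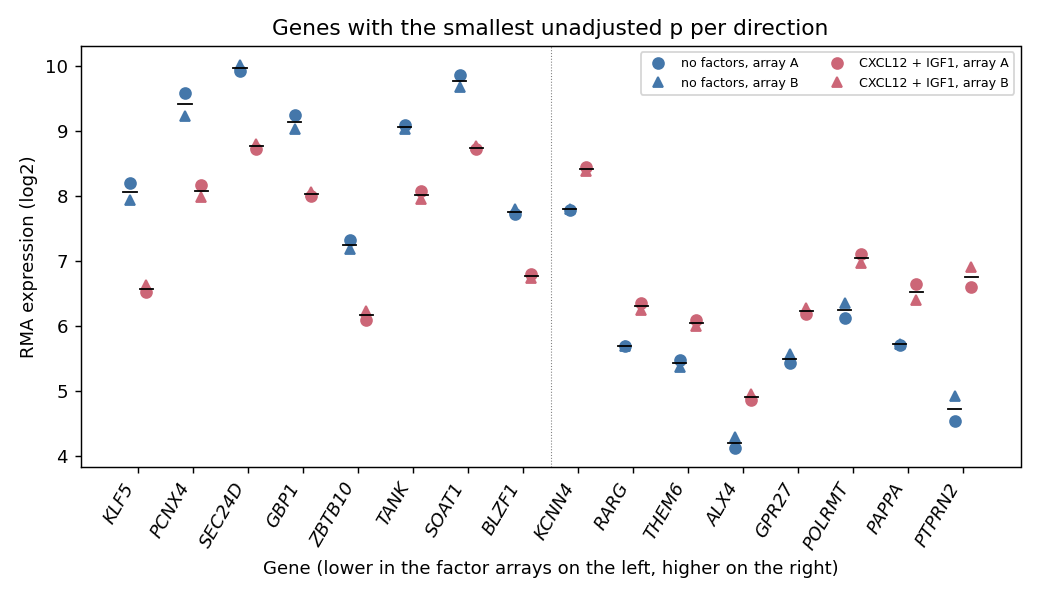
RMA expression on the log2 scale (y axis) of the 8 genes with the smallest unadjusted p in each direction (x axis), for the 2 arrays of each group, with a black bar at the mean of the group. In all 16 genes both arrays of a group lie on the same side of the other group, which follows in part from choosing them by p, and the gap is widest for PTPRN2 at 2.03 log2.

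For the receptors of the factors, the values of the groups overlapped. CXCR4, the main receptor of CXCL12, measured 8.18 and 6.56 on no-factor arrays A and B and 6.27 and 7.42 on factor arrays A and B. Its difference of -0.52 had a standard error of 0.66 and became 0.29 without no-factor array A and 0.05 without factor array A, and other CXCR4 sets gave 0.00 and -0.28. ACKR3, the other CXCL12 receptor, differed by -0.70 with a standard error of 0.45, and by -0.34 without no-factor array A and -0.13 without factor array A. IGF1R, the receptor of IGF1, differed by 0.31 with a standard error of 0.19, and by 0.17 and 0.12 without those arrays. INSR differed by -0.18, which became 0.06 without no-factor array A. Of the adaptor proteins downstream, IRS1 differed by -0.34 with a standard error of 0.11 and lay lower on both factor arrays, and IRS2 differed by -0.12, or 0.01 as a mean of its probe sets. SRC, the tyrosine kinase that acts downstream of both receptors, differed by 0.04 with a standard error of 0.17. Its sign turned after median centring, after cyclic loess, without no-factor array A (-0.15) and without factor array B (-0.04). In the list of CXCL12 and IGF1 receptors and ligands, 11 of 18 measured genes lay higher and 7 lower with the factors, and 0 passed adjusted over the list alone.

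The list of Src family kinases and substrates held 21 measured genes, 13 higher and 8 lower, with a median of 0.04, a mean of -0.07 and 0 genes past the test adjusted over the list alone (camera adjusted p = 0.998, direction down). Its members with the largest differences were the scaffold protein NEDD9 at -1.37 (standard error 0.54, and -0.67 without factor array A) and the kinase YES1 at -0.85 (standard error 0.22), with -0.66 and -0.27 on their other sets above the dim limit. The PI3K-AKT pathway list had a median of 0.08 over 16 genes, where the growth inhibitor TSC2 differed by 0.50, but by -0.24 on a dimmer set and 0.13 as a mean of its sets, and the phosphatase INPP4B by -0.56. INPP4B had a standard error of 0.40 and overlapping groups, and differed by -0.20 without no-factor array A and -0.09 without factor array A. In the list of FOXO and starvation-induced genes, 10 of 15 lay lower, among them CITED2 at -1.02 and CCNG2 at -0.48 (camera adjusted p = 0.362).

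Cell cycle inhibitors and quiescence genes fell as a list, with 12 of 13 measured members lower with the factors, a median of -0.35 and a camera adjusted p of 7.33e-05. The estimated correlation was -0.017, below the preset 0.01. With it the adjusted p in camera was 0.999 (unadjusted p = 0.0375), and fry gave an adjusted p of 0.19. The loss in camera goes with the 2 residual degrees of freedom used there, as the estimated correlation lay below the preset value. That estimate rests on the same 2 degrees of freedom, so correlation between the genes stays open. RBL1, a pocket protein related to the retinoblastoma protein, differed by -0.99 with a standard error of 0.20, and RB1, which encodes the retinoblastoma protein, by -0.71 with a standard error of 0.13, and by -0.25 on a dimmer set. These 2 genes passed adjusted over the list alone (adjusted p = 0.0327 each in limma), and 0 passed over all genes. At an unadjusted p under 0.05, 5 members were lower, the others being the antiproliferative gene TOB1 at -0.58, the kinase gene PLK2 at -0.50 and CCNG2 at -0.48, or -0.32 and -0.18 on other CCNG2 sets. Without factor array B, TOB1 differed by -0.29 and CCNG2 by -0.28. In the list of cell cycle and proliferation genes, 27 of 45 lay higher and 18 lower, with a median of 0.09 and a camera adjusted p of 0.998. The spindle checkpoint gene MAD2L1 differed by -0.76 there and the transcription factor FOXM1 by 0.45, or 0.24 without no-factor array A.

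YAP-TEAD targets also fell as a list, with 13 of 19 measured genes lower, a median of -0.13 and a camera adjusted p of 0.0343. With an estimated correlation, here 0.23, the adjusted p in camera was 0.999, and fry gave an adjusted p of 0.949. The call ended without no-factor array A (adjusted p = 0.0962), without factor array A (adjusted p = 0.545), after cyclic loess (adjusted p = 0.119) and with the dimmest 50% of sets left out (adjusted p = 0.14), in a range of 0.00502 to 0.545 over 15 alternatives. Tissue factor, F3, differed by -1.03, TGFB2 by -0.82, the matricellular gene CCN1 by -0.61, CRIM1 by -0.58, the stress gene GADD45A by -0.41 and ANKRD1 by -0.34, each at an unadjusted p under 0.05. A further TGFB2 set above the dim limit gave -0.53. IGFBP3, an IGF-binding protein in the same list, differed by 0.50 in the other direction, or 0.31 without no-factor array B. F3 differed by -0.60 without factor array A and CRIM1 by -0.36 without no-factor array A.

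Genes associated with bone metastasis showed 10 of 21 measured members higher and 11 lower, with a median of -0.22 and a camera adjusted p of 0.332. VCAM1, an adhesion molecule that binds osteoclast precursors and leukocytes, was the 1 member past the test adjusted over the list alone (adjusted p = 0.0276 in limma). It measured 4.84 ± 0.15 (SD, n = 2) without and 3.99 ± 0.01 (SD, n = 2) with the factors, near the limit of 4.14 below which sets were left out. The cytokines IL11 and IL6, which promote osteoclast formation, differed by -0.93 and -0.97, and the collagenase MMP1 by -0.79. A dimmer IL11 set gave -0.48. Without factor array A the difference of IL6 was -0.61, and without no-factor array A that of MMP1 was -0.39. BMP2, a bone morphogenetic protein, differed by 1.28 with a standard error of 0.48, and by 0.73 without factor array A. It measured 4.03 on no-factor array A, under the limit of 4.14 for dim sets. The list for lung or brain metastasis had a median of 0.09 over 22 genes, and VCAM1 passed adjusted over that list alone as well (adjusted p = 0.0289 in limma). The inhibitor of differentiation ID3 differed there by 1.52 with a standard error of 0.59, which became 0.64 without factor array A. KYNU, an enzyme of tryptophan breakdown, differed by 1.40 with a standard error of 0.97, its groups overlapped, and the difference became 0.13 without no-factor array A.

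Inflammatory genes included CXCL8, a neutrophil chemokine, at -0.99 and IL6 at -0.97, and 15 of 23 measured NF-kB targets lay lower (camera adjusted p = 0.291). The adjusted p of this list was 0.0322 without no-factor array A and 0.0331 without factor array B, in a range up to 0.935 over 15 alternatives. Among 37 interferon-stimulated genes GBP1 passed adjusted over the list alone (adjusted p = 0.0164 in limma), and the antiviral gene RSAD2 differed by -0.97 with a standard error of 0.46, and by -0.39 without factor array A. The class II antigen genes HLA-DRA and HLA-DRB1 differed by 1.15 and 0.91, with standard errors of 0.50 and 0.61, and by 0.52 and 0.04 without factor array A (antigen presentation, 13 of 20 higher, camera adjusted p = 0.584). That list gave an adjusted p of 0.0322, upward, without no-factor array A, and up to 0.949 over 15 alternatives. In the extracellular matrix list the proteoglycan SPOCK1 differed by 1.40 with a standard error of 0.68 and overlapping groups, and by 0.57 without no-factor array A. THBS1, which encodes thrombospondin, differed by -1.22, although the other THBS1 sets gave -0.43, -0.29, -0.18 and 0.08. The repressor ZEB2 of the mesenchymal list differed by -1.23 and TGFBI by 0.60. The adhesion molecule EPCAM of the epithelial list differed by -1.09, or -0.68 without factor array A, and the mucin MUC1 by -0.71, or -0.43 and -0.27 on dimmer sets. The adhesion molecule L1CAM differed by -1.33, or 0.27 on the L1CAM set with the smallest p, and by -0.09 without factor array A. NRCAM, of the same family, differed by 1.20, or 0.78 without factor array A.

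Stress genes depended on which no-factor array was used. The list of ATF4 targets, genes induced by amino acid stress, had 14 of 26 genes higher and a camera adjusted p of 0.998. The direction in camera was down without no-factor array A and up without no-factor array B, at the preset correlation of 0.01. The estimated correlation of this list was 0.60, and with it the adjusted p in camera over all 4 arrays was 0.999. Its members with the largest differences were the cysteine-forming enzyme CTH at -0.76, or -0.08 on its other set, and the stress regulator NUPR1 at 0.60, or 0.37 without no-factor array A. Chaperones of the unfolded protein response had 12 of 19 genes lower, among them HSPA5, the main chaperone of the endoplasmic reticulum, at -0.40, or -0.22 without no-factor array B. The camera adjusted p of the chaperones was 0.332 at the preset correlation and 0.999 at the estimated correlation, which was 0.30. Without no-factor array A the direction in camera was also down. In the hypoxia and glycolysis list, with 17 of 34 genes higher, VEGFA differed by -0.50, with -0.05 to -0.39 on its other sets, and the glycolytic enzyme ALDOC by 0.56.

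Of the 34 lists, 2 passed camera at the preset correlation, 0 with an estimated correlation, 0 in fry and 0 in fry's test for changes in either direction, where the smallest adjusted p was 0.145. In 18 lists the median, the mean and the direction of camera did not all have the same sign, and in 7 of them the median and the mean themselves differed in sign. Among markers of other cell types, leukocyte markers had a median of 0.22 over 11 measured genes (camera adjusted p = 0.515), fibroblast markers 0.08 over 9 (adjusted p = 0.998) and endothelial markers 0.12 over 5 (adjusted p = 0.724). Markers of luminal breast lines had a median of 0.06 over 13 (adjusted p = 0.998).

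**Figure D2:**
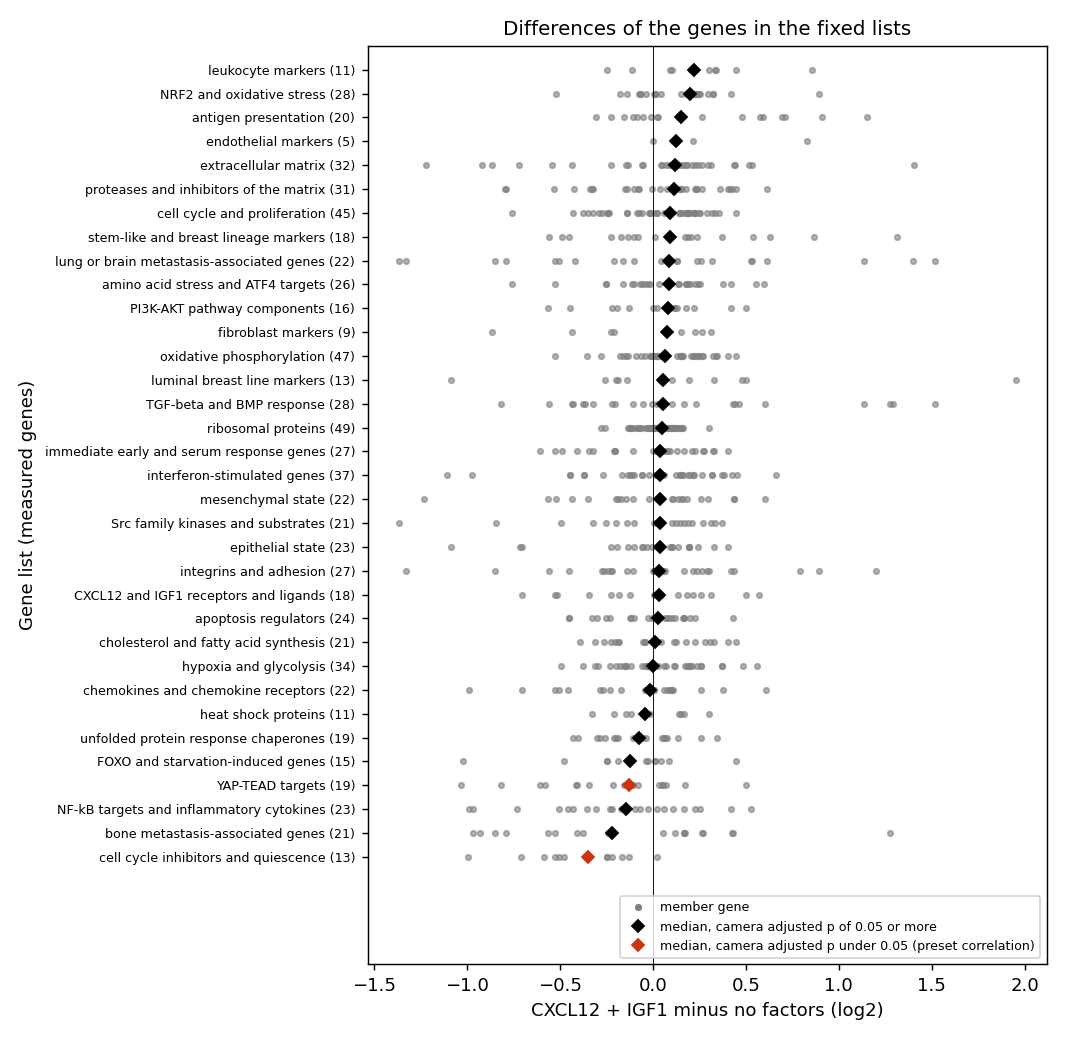
Difference between the groups on the log2 scale (x axis) for the measured members of each gene list (y axis, number of measured genes in brackets), with a grey point per gene and a diamond at the median. The medians of cell cycle inhibitors and quiescence (-0.35) and of YAP-TEAD targets (-0.13), in red, are those with a camera adjusted p under 0.05 at the preset correlation, and both calls were lost with an estimated correlation.

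The most similar pair of arrays came from different groups. Across genes, which are not independent replicates, the correlation was r = 0.9895 between the no-factor arrays and r = 0.9872 between the factor arrays. It was r = 0.9898 between no-factor array B and factor array B, and lowest, r = 0.9745, between no-factor array A and factor array A. AGR2, a disulfide isomerase of secretory cells, measured 4.52 on no-factor array A and 10.37, 9.59 and 9.20 on no-factor array B, factor array A and factor array B. Its difference of 1.95 with a standard error of 1.92 became -0.97 without no-factor array A. The difference between factor array A and no-factor array A correlated with that between the B arrays at r = 0.04 across genes, and the 2 differences had the same sign in 56.0% of genes. With the letters crossed, factor array A minus no-factor array B correlated with factor array B minus no-factor array A at r = 0.53. The labels do not pair the arrays, so neither value alone shows how well the group difference repeats. The ACTB control sets, which compare the 3' with the 5' end of the transcript as a sign of RNA integrity, differed by 1.63 and 1.71 on no-factor arrays A and B and by 1.52 and 1.53 on factor arrays A and B. The GAPDH control sets differed by 0.56 and 0.42 on no-factor arrays A and B and by 0.43 and 0.57 on factor arrays A and B.

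**Figure D3:**
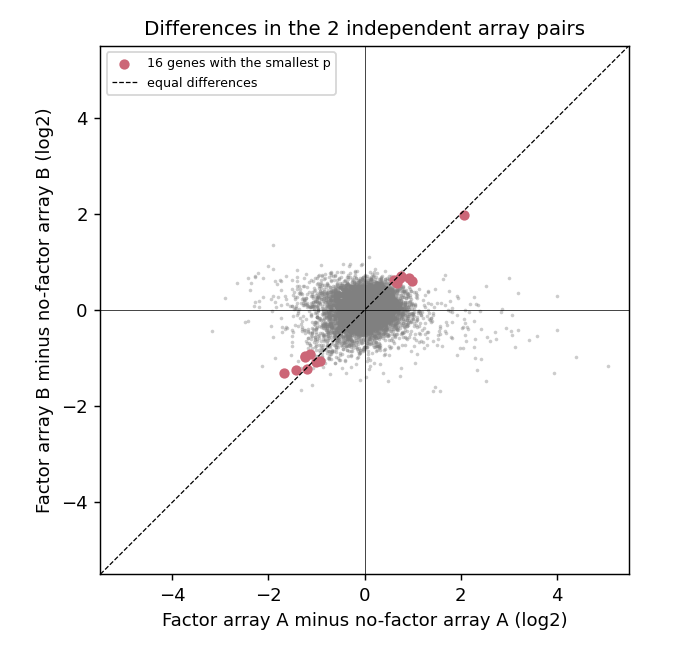
Difference between factor array A and no-factor array A (x axis, log2) against that between factor array B and no-factor array B (y axis, log2) for each of the 9623 genes in grey, with the dashed line at equal differences. The 16 genes with the smallest p, in red, lie near the line because they were chosen by p, while over all genes the 2 differences correlate at r = 0.04. The labels do not pair the arrays, and with the letters crossed the correlation is r = 0.53.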

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

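No gene passed the adjusted threshold in limma under any of the 16 alternatives, and the smallest adjusted p of a named gene was 0.218. The signs of 81 of 92 named genes held under every alternative, but 49 differences shrank by over 1.5 times or turned when 1 array was left out, 32 of them without no-factor array A and 30 without factor array A. At an unadjusted p under 0.05, genes higher with the factors numbered 378 with the dimmest 50% of sets left out, where fewer genes were tested, 425 after median centring and 417 after cyclic loess, which remove a shift between the arrays. With each array left out in turn the count of genes at an unadjusted p under 0.05 ranged from 372 to 1171, of higher genes from 126 to 551, of lower genes from 246 to 620 and of lists from 1 to 5. Without no-factor array A the counts were lowest and 5 lists passed, those of quiescence, ATF4 targets, chaperones, antigen presentation and NF-kB targets. Without no-factor array B there were 813 genes, 385 of them higher, and without factor array A 417 higher genes and 1 list. The lone remaining array of a group was then assumed to vary like the other group.

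The labels do not say that the letters A and B pair the arrays, and the deviations of same-letter arrays from their group means correlated at -0.50 across genes. With the letter as a replicate block, 582 genes lay at an unadjusted p under 0.05 (221 higher, 361 lower) and 0 passed the adjusted threshold. With the opposite pairing as a block, chosen after seeing the data, limma called 0 genes and gave 1920 at an unadjusted p under 0.05, 1051 of them higher.

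The 2 called lists became 1 with the dimmest 50% left out and 1 after cyclic loess, where YAP-TEAD targets were lost, 0 with an estimated correlation and 0 in fry. The quiescence list passed camera in 15 of 15 alternatives at the preset correlation, with adjusted p values from 4.28e-05 to 0.00152. With each array left out, the adjusted p of the list of ATF4 targets ranged from 0.0139, downward without no-factor array A, to 0.935, and was 0.0288 upward without no-factor array B. The cause was not tested.

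The following genes changed sign, and the cause was not tested. SRC gave -0.0006 after median centring and -0.0182 after cyclic loess. As a mean of probe sets IRS2 gave 0.0067 and HSPA4 0.021. PDIA6 gave 0.0754 with the brightest set of any kind. On the set with the smallest p HSPA4 gave 0.32 and L1CAM 0.27. With each array left out, the difference ranged from -1.34 to 0.29 for CXCR4, from -0.42 to 0.0563 for INSR, from -0.15 to 0.23 for SRC, from -0.0755 to 1.79 for ITGB2, from -0.97 to 4.88 for AGR2, from -1.84 to 0.26 for SPINK4 and from -1.004 to 0.13 for COL5A1. Signal over background was not used here, so values near the lower end of the scale have an unknown floor.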

Other observations

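All tests in this part were chosen after the results were seen. Several of the largest differences lay within groups. SEL1L3 measured 5.03 and 8.29 on no-factor arrays A and B and 9.05 and 7.86 on factor arrays A and B. The aldehyde dehydrogenase ALDH3A1 measured 4.55, 7.78, 8.96 and 6.79 on the same arrays in that order. PTGS2, the inducible cyclooxygenase, measured 4.56, 7.74, 7.10 and 6.25, and the phospholipase PLCB1 measured 4.41, 7.54, 8.36 and 6.22. The opposite direction between the A arrays held for the matrix protein gene MATN2, which measured 8.53, 7.43, 6.10 and 8.10, and for the lipoxygenase ALOX5 with 7.26, 6.07, 4.61 and 6.64.

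Targets of ATF4, the transcription factor of amino acid stress, separated the no-factor arrays. Of 26 measured targets, 23 were higher on no-factor array B than on array A, with a median of 0.40 that exceeded 100% of 10000 random lists matched on mean expression. DDIT3 measured 9.17 on no-factor array A and 10.39 on array B, ASNS, which makes asparagine, 10.22 and 10.87, and the pseudokinase TRIB3 8.97 and 9.88. Chaperones of the unfolded protein response were higher on no-factor array B in 16 of 19 genes, with a median of 0.37 that exceeded 100% of random lists. On the factor arrays the medians of array B minus array A were 0.10 for ATF4 targets and 0.12 for the chaperones, above 93.5% and 95.5% of random lists. On no-factor array B, 33 of these 45 genes lay above both no-factor array A and factor array A, by a median of 0.168 over the 45, but both lists were picked because they were high there. Antigen presentation genes went the other way between the no-factor arrays, with a median of -0.17 that exceeded 0.14% of random lists. Extracellular matrix genes had a median of -0.14 between the no-factor arrays and 0.15 between the factor arrays, above 0.14% and 99.4% of random lists. Fibroblast markers, a list of another cell type, were higher on factor array B than on factor array A in 9 of 9 genes, with a median of 0.35 that exceeded 99.8% of random lists, and had a median of 0.07 between the no-factor arrays, above 82.4%. These percentiles describe the arrays and carry no replicate error. The random lists held unrelated genes, while the estimated correlation within the lists above ran from 0.10 (antigen presentation) to 0.60 (ATF4 targets). Lists of genes that vary together reach extreme percentiles more easily, so the percentiles are no test of the lists.

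No-factor array B and factor array B lay between no-factor array A and factor array A on the first principal component (61.1% of the variance). A mixture of the cell populations of the 2 end arrays is a candidate explanation. On the second component (26.0%) the B arrays lay outside both ends on opposite sides, at 11.3 and -17.6 against 2.29 and 4.01. The end arrays span the first component, so the second holds mainly the difference between the B arrays, array noise included. It therefore cannot decide on a mixture. Over 79 genes higher and 57 lower by more than 1.5 log2 on factor array A, a mixture predicts 1 linear position for all genes of an array. On no-factor array B the median positions were 0.504 for higher genes (quartiles 0.332 and 0.678) and 0.559 for lower genes (quartiles 0.494 and 0.671). Their difference was -0.055 (95% bootstrap interval -0.133 to 0.0045), and -0.126 at a threshold of 2 log2, with 8 of the 136 genes outside both ends. An even shift on the log2 scale was argued against there, for these genes, by a difference of 0.259 (0.193 to 0.337). The bootstrap intervals took genes as independent and held no array noise. On factor array B the quartiles were 0.237 and 0.464 around 0.342 for higher genes and 0.314 and 0.694 around 0.55 for lower genes. The differences were -0.208 (-0.278 to -0.083) for a mixture and 0.151 (0.0833 to 0.253) for an even log2 shift. At thresholds of 1 and 2 log2 they were -0.216 and -0.0929 against 0.0632 and 0.307. Both intervals excluded 0, so for these genes neither a mixture alone nor an even log2 shift alone described this array exactly. Both also reached inside the bound of 0.15, so these cannot be told apart. A mixture as a part of the cause stays open for both arrays. The quartiles lay within 0.15 of the median, a bound applied after these were seen, in only 1 kind of gene on each array. Array noise, part of this spread and of the second component, was not measured, and a biological cause was not tested.

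The granzyme gene GZMA and the lymphocyte receptor gene CD96 measured 7.67 and 7.06 on factor array A against 3.66 and 3.86 on no-factor array A, which could come from RNA of leukocytes. Over 19 leukocyte markers from the fixed list, 11 of which passed the filter on dim sets here, the median difference between these arrays was 0.0653, and PTPRC, the pan-leukocyte phosphatase, differed by 0.112. The T cell markers CD3D, CD3E and CD2 differed by 0.54, -0.01 and -0.07. On factor array A, PTPRC measured 2.83, LYZ 3.57, TYROBP 3.29 and CORO1A 4.15, while ITGB2, the integrin chain, was an exception with a difference of 2.31. These values argue against leukocyte RNA, while expression of GZMA and CD96 in a subpopulation of the line and cross-hybridisation of their probes stay open and untested.

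In the dimmest 25% of genes, 223 were higher and 52 lower with the factors at an unadjusted p under 0.05, and in the brightest 25% 82 were higher and 229 lower. Cyclic loess, which by construction removes a trend with brightness between arrays, narrowed the gap in the share of higher genes between these sets from 54.7 to 23.8 percentage points (95% interval 15.2 to 32.0, with genes taken as independent), with the share going from 81.1% to 50.9% among the dimmest genes and from 26.4% to 27.2% among the brightest, while after median centring these shares were 71.6% and 13.3%, a gap of 58.3 points. Over all genes, loess took the median difference from 0.0962 to 0.0128 in the dimmest 25% and from -0.004 to 0.0051 in the brightest 25%. A difference between the arrays in the distribution of dim values that RMA left was argued against as the whole cause only for genes at an unadjusted p under 0.05. Among these the brightest genes kept their share under loess, and this cause stays open for the dim genes. The other sets of the genes at an unadjusted p under 0.05 shared the sign of the tested set in 76.4% (95% binomial interval 72.7 to 79.7, with sets taken as independent), against 64.8% in the remaining genes. This argued against probe sets that respond on their own as the whole cause over these genes, but the count was not split by brightness. A part stays open, as the other sets moved by a median of 0.15 in that direction and the tested sets by 0.45. A biological shift of dim genes was not tested and stays open.

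The 4 arrays can be split into 2 and 2 in 3 ways, which is too few for a share under 0.05. The real split gave 1220 genes at an unadjusted p under 0.05, and the highest of the others, no-factor array A with factor array B, gave 666. The real split was the 1 split of 3 with that many genes.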
